A study of Saccharomyces cerevisiae with 9 samples.

How the data were processed

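Gene expression was measured in Saccharomyces cerevisiae cultures on 1-colour oligonucleotide arrays, with 3 cultures in each of 3 groups and 1 array per culture. Per the labels' protocols, cells grown in rich YPD broth received bisphenol A (BPA) dissolved in ethanol at mid-exponential phase, at 50 or 300 mg/L. Control cultures received the same volume of ethanol, and all were exposed for 180 min. Total RNA was purified on silica columns and turned into biotin-labelled RNA by in vitro transcription from the 3' end. The strain, cell density and growth rate are not given in the sources used here. No hybridisation date or batch is given either, so none could be tested.

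The deposited values are log2 expression values, 1 per probe set and array. Per the submitters' processing notes, RMA, affy and limma were used, with no versions or roles given. RMA corrects the background, makes the distributions of probe intensities equal between arrays and then summarises the probes of a probe set. The summarised values need not be equal in distribution: their medians ran from 4.42 to 4.58 in the control and 50 mg/L arrays and from 4.86 to 4.96 at 300 mg/L. The scaling holds no measure of total mRNA per cell, so every change below is relative to the other transcripts of the same array. The values carry no counts, and the number of arrays limits the precision.

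The table holds 10928 probe sets. The platform annotation lists 7245 of them, 7244 with 1 gene symbol and 1 with several, and 3683 are unnamed here. Through gene identifiers, 5498 probe sets matched the R64 reference gene table of S. cerevisiae, which was used for names and gene order only, and 12 symbols were updated. The array also carries probe sets for the fission yeast Schizosaccharomyces pombe, of which 1746 were named. For a gene with several probe sets, the one with the highest mean over all arrays was kept, leaving 5449 genes. Of 47 such genes, 11 had probe sets that differed in whether they passed the test at 300 mg/L, and 0 had calls in opposite directions. A further 118 genes rest on probe sets that can match related sequences.

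The S. pombe probe sets served as background. A gene was taken as not above background on an array when it lay at or under the 95th percentile of those probe sets. Where all 3 arrays of a group were not above background, the fold is a bound: the mean of the brighter group against the mean, over the dim arrays, of the higher of that percentile and the gene's own value.

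Changes were tested in R 4.3.3 with limma 3.58.1 (lmFit, contrasts and eBayes) over all 9 arrays, which share one estimate of each gene's spread. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Errors of log2 changes are standard errors from that fit, and errors of levels are SDs over 3 arrays. A moderated F test asked for any difference among the 3 groups. For 40 gene lists, camera compared each list with the other genes at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. Camera with a correlation estimated per list and fry, a rotation test of a list's own genes, were alternatives. Camera with an estimated correlation tests on the 6 residual degrees of freedom, so its p can rise where the estimate is near 0.01. The meiosis list at 300 mg/L is such a case, with an estimate of 0.015. For the other lists called at 300 mg/L against control, the estimate ran from 0.055 to 0.737, above the preset of 0.01. Their p at the preset correlation may therefore be too small. A list needed at least 5 measured genes. Figures were drawn with matplotlib 3.10.9.

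The groups, tests, lists and rule for named genes were fixed before the data were examined. The rule takes, for each dose against control, the 10 largest rises and 10 largest falls among genes past the threshold whose 3 treated values all lie on one side of all 3 control values. For 300 against 50 mg/L it takes 5 of each. For each list described, it takes the 2 largest rises and 2 largest falls among members past the threshold, or the 2 members with the smallest p where none passed. A probe set with several genes is not named.

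The pipeline was tested on simulated data: 9 arrays of 5449 genes, with 200 genes changed, over 20 runs. For 3 arrays against 3, it recovered 40.7% of genes changed by 1.25-fold, 93.1% at 1.5-fold, 99.4% at 2-fold and 100% at 4-fold, and 5.48% of calls were false. A list of 30 genes shifted by 0.3 on the log2 scale was found in 20 of 20 runs, and an unshifted list in 2. These data have no correlation between genes beyond the simulated shift, so they do not test the preset correlation.

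The replicate numbers were checked for pairing by correlating deviations from the group means. For control and 50 mg/L the 3 same-numbered pairs ran from 0.19 to 0.42, all over 0.1, and the 6 other pairs from -0.43 to 0.18. The numbers were therefore taken to pair these 2 groups. Between 50 and 300 mg/L, arrays with different numbers reached 0.40, so a correlation of this size does not settle a pairing. That was decided from the correlations, but after the calls of the block over all 9 arrays had been seen. The pairing comes from the data, since the labels do not say what a number shares.

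Alternatives covered the arrays in the fit, a replicate block, the prior, array weights, repeated normalization, centring, dim genes, probe sets, thresholds and each array left out in turn. Centring on S. pombe probe sets or on hybridization spike-ins, and the replicate block in a fit of only the control and 50 mg/L arrays, were added after seeing the data.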

Results

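The series asks how the yeast transcriptome responds to bisphenol A, the monomer of polycarbonate plastics, at a lower and a higher concentration. It holds 9 arrays: 3 control, 3 at 50 mg/L and 3 at 300 mg/L BPA. Between 5363 and 5418 of the 5449 genes lay above background on each array. The first principal component carried 80.2% of the variance and separated the 300 mg/L arrays from the other 6. The second, with 8.61%, set replicate 2 of the 50 mg/L group apart. Correlations across genes ran from 0.995 to 0.998 within the control group, from 0.991 to 0.996 at 50 mg/L and from 0.994 to 0.997 at 300 mg/L. The median SD of a gene was 0.07, 0.13 and 0.08 on the log2 scale in these groups, so the 50 mg/L group was the most variable. The labels call the replicates biological, without saying how the cultures were started.

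**Figure D1:**
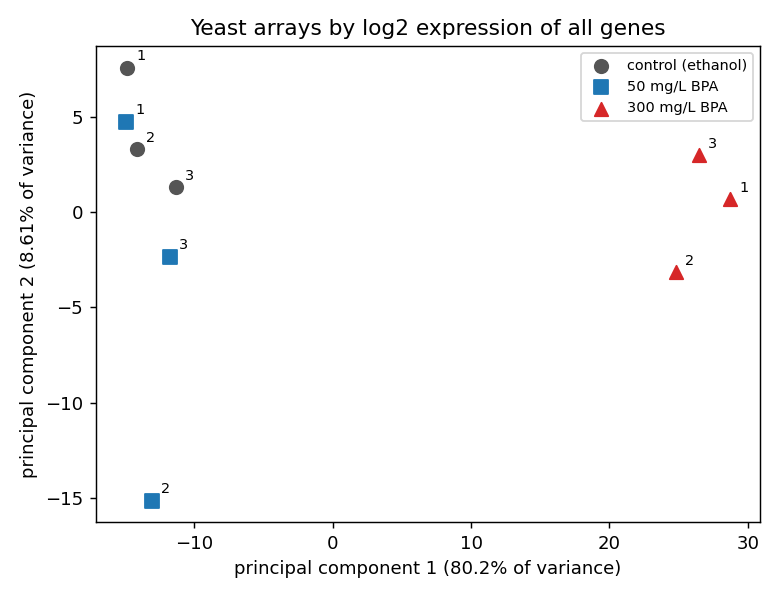
Principal components of the log2 values of all genes, 1 point per array with its replicate number, the share of variance on each axis. The 3 arrays at 300 mg/L lie between 24.8 and 28.7 on the first component and the other 6 between -14.9 and -11.3.

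The comparison of 300 mg/L BPA with control asks which genes respond to the higher dose. By camera at the preset correlation, lists of sporulation and meiosis, iron uptake, drug efflux and ribosome assembly were higher, and respiratory, glycolytic and reserve carbohydrate lists lower. With an estimated correlation, from 0.015 to 0.737 per list and on 6 residual degrees of freedom, 0 of the 17 lists called passed. Fry called 29 lists, 16 of the 17 among them, but not general stress (adjusted p = 0.0692). The median of the meiosis list did not stand apart from random lists matched on control level. MAM1, which directs chromosome attachment in meiosis, rose from 3.47 ± 0.27 to 8.36 ± 0.75 (SD, n = 3), a 29.7-fold change. SPR3, a sporulation septin, and SRT1, a prenyltransferase of dolichol synthesis, each rose 25.1-fold, and SPO19, a protein of spore membrane formation, rose 19.2-fold. GPH1, the glycogen phosphorylase, fell by 2.01 ± 0.22 (SE) on the log2 scale, and HXK1, a hexokinase, fell by 1.85 ± 0.19. In all, 2872 of 5449 genes passed the test, 1500 higher and 1372 lower, and 294 of them changed at least 2-fold, 229 higher and 65 lower.

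YLR412C-A rose by 3.95 ± 0.29 on the log2 scale, though 2 of 3 control arrays were not above background, so its size is loose, and SPS1, a kinase of spore wall formation, by 3.54 ± 0.16. ECM23 rose at least 8.46-fold, the sporulation gene SPS2 at least 10.8-fold and SAE3, a meiotic recombination factor, at least 9.72-fold, since all 3 control arrays were not above background. ATG41, an autophagy factor, was already well expressed in controls at 6.99 ± 0.02 and rose to 10.44 ± 0.55 (SD, n = 3). Among the falls, the peptide transporter gene OPT2 fell by 1.89 ± 0.16, WSC4 by 1.88 ± 0.15 and the hexose transporter HXT4 by 1.70 ± 0.18. ARO10, a decarboxylase of amino acid breakdown, fell by 1.62 ± 0.08, the glutamate decarboxylase GAD1 by 1.61 ± 0.23 and the glycogen synthase GSY1 by 1.58 ± 0.16. HXT7 fell by 1.56 ± 0.17, on a probe set that can match related transporters, and the phosphoglucomutase PGM2 by 1.56 ± 0.23. Adjusted p for these 20 genes ran from 1.32e-08 for SRT1 to 0.000359 for PGM2.

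**Figure D2:**
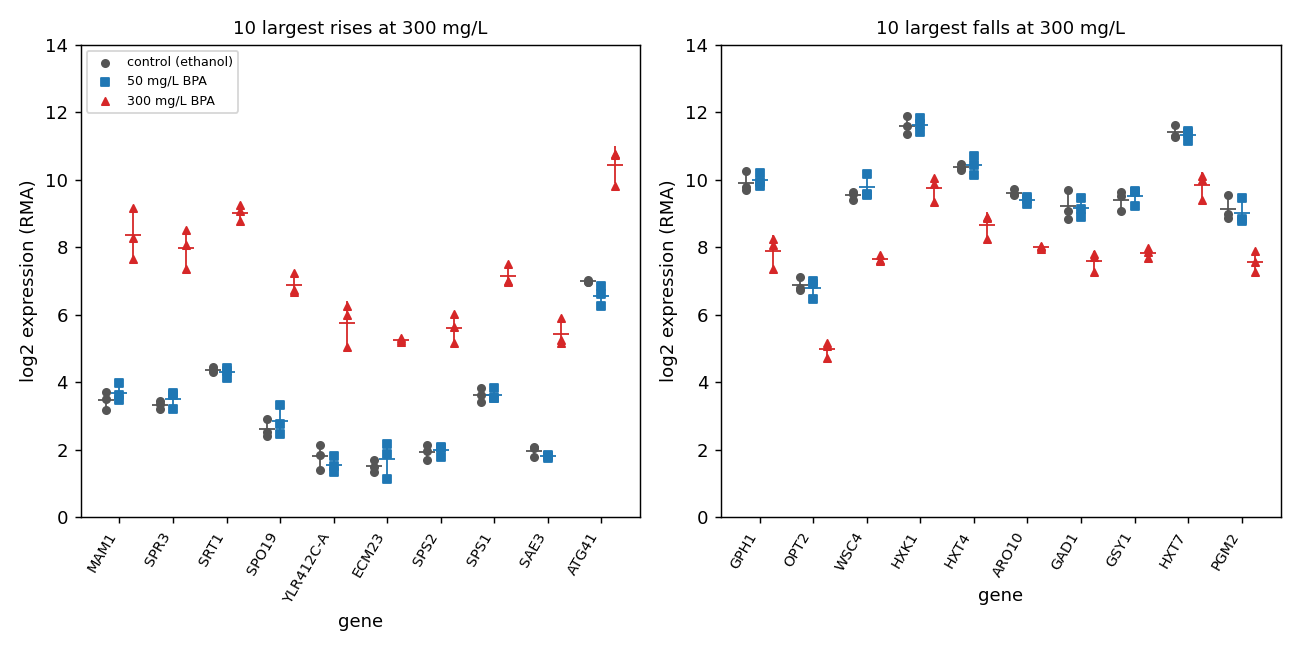
Log2 expression on each array of the 10 genes with the largest rises (left) and falls (right) at 300 mg/L, points for arrays, bars for the mean and SD of 3. All 3 values at 300 mg/L lie on one side of all 3 control values for each gene, which the selection required.

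Respiration was lower at 300 mg/L at the transcript level. Of 40 measured oxidative phosphorylation genes, 37 fell and 0 rose. RIP1, the Rieske subunit of complex III, fell 2.83-fold, and SDH1, a subunit of succinate dehydrogenase, fell by 1.42 ± 0.10 on the log2 scale. In the TCA cycle list 14 of 16 fell and 0 rose, with KGD2 down by 1.09 ± 0.08. Of 66 mitochondrial ribosomal protein genes, 37 fell, such as MRPS5, by 1.05 ± 0.07, and MRPS35, by 0.89 ± 0.12, while 2 rose, MRPL37 by 0.37 ± 0.08 and MRPL51 by 0.22 ± 0.07. Camera put these lists below the other genes, with adjusted p of 1.43e-13, 2.57e-06 and 6.71e-07. With an estimated correlation the adjusted p were 0.532, 0.532 and 0.536.

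Genes of sugar storage and glycolysis were lower too. In the trehalose and glycogen list 15 of 20 fell and 1 rose. The riser was GAC1, a regulator of glycogen synthesis, at 2.05 ± 0.47. In the glycolysis and fermentation list 12 of 17 fell and 0 rose, among them TDH1, by 1.29 ± 0.16, and ENO1, by 1.21 ± 0.11. Of 34 general stress genes 19 fell, led by GPH1 and HXK1, and 4 rose, led by GAC1 and by the chaperone HSP42, at 1.22 ± 0.29. Camera's adjusted p were 0.000108, 0.000850 and 0.00437, and 0.532, 0.532 and 0.647 with an estimated correlation. Hexose transporters moved both ways. HXT1 rose by 2.50 ± 0.19 and GAL2 by 2.46 ± 0.11, while HXT4 and HXT7 fell. Of 13 measured members 9 rose and 3 fell (adjusted p = 0.115 by camera and 0.000573 by fry).

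Ribosome assembly genes rose. Of 77 measured, 65 rose and 0 fell, with 68 adjusted over the list alone. IMP4, of the small subunit processome, rose by 2.01 ± 0.16, and the nucleolar protein gene NSR1 by 1.09 ± 0.13. Of 19 RNA polymerase I and III subunit genes 13 rose and 0 fell, with RPA34 at 0.82 ± 0.12 and RPC37 at 0.79 ± 0.11. Camera's adjusted p were 4.57e-12 and 0.000854, and 0.532 for both with an estimated correlation. Control probe sets for ribosomal RNA moved in the same arrays: the 3' end of 25S rRNA was higher by 1.03 ± 0.19 and its 5' end by 0.21 ± 0.15, with adjusted p of 0.0019 and 0.375.

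Iron and drug efflux genes rose. Of 28 genes of the iron regulon 23 rose and 1 fell. FRE1, a ferric and cupric reductase, rose by 1.98 ± 0.14, and the siderophore transporter SIT1 by 1.95 ± 0.15, while FET5 fell by 0.17 ± 0.07. Of 24 genes in the pleiotropic drug resistance list, named after the transcription factors Pdr1 and Pdr3, 19 rose and 2 fell. HXT11 rose by 2.61 ± 0.30 and RTA1 by 2.52 ± 0.17, while TPO4 fell by 0.38 ± 0.14 and QDR2 by 0.29 ± 0.10. Camera's adjusted p were 4.17e-08 and 1.04e-05, and 0.462 and 0.532 with an estimated correlation.

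In the meiosis and sporulation list 22 of 29 genes rose and 1 fell, SPS4, by 0.82 ± 0.09. Its largest rises were SPR3, at 4.65 ± 0.24, and SPO19, at 4.26 ± 0.22. Camera's adjusted p was 5.39e-06, and 0.134 with an estimated correlation, though the estimate was only 0.015. Fry gave an adjusted p of 1.51e-05. The list's median change of 0.64 lay within the central 95% of 10000 random lists matched on control level, which ran from 0.16 to 0.71. The median of those random lists was 0.40, so other genes of similar control level rose as well. Only the list's own genes were left out of the pool, so other meiotic genes, such as MAM1, were not. In the list, SPO74 and MEI5 were among the risers but lay at background on all arrays of both groups.

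Another 6 lists were lower by camera at 300 mg/L. Among vacuolar hydrolases 7 of 11 fell, led by the aminopeptidase APE1, by 1.36 ± 0.15. Among purine and one-carbon genes 10 of 16 fell, led by ADE17, by 1.00 ± 0.17. Among unfolded protein response genes 10 of 17 fell, led by the disulfide isomerase MPD1, by 1.01 ± 0.13, and 1 rose. Among proteasome subunits 15 of 32 fell, led by PRE8, by 0.66 ± 0.10. Among autophagy genes 9 of 22 fell, led by ATG33, by 0.83 ± 0.11, and 3 rose, led by ATG10, at 0.78 ± 0.16. Among G1/S and DNA replication genes 13 of 31 fell, led by the cyclin PCL1, by 1.07 ± 0.11, and 3 rose. Camera's adjusted p ran from 0.00254 to 0.0429, and from 0.532 to 0.608 with an estimated correlation. Against random lists matched on control level, the medians of the proteasome, unfolded protein response and G1/S lists lay within the central 95%.

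**Figure D3:**
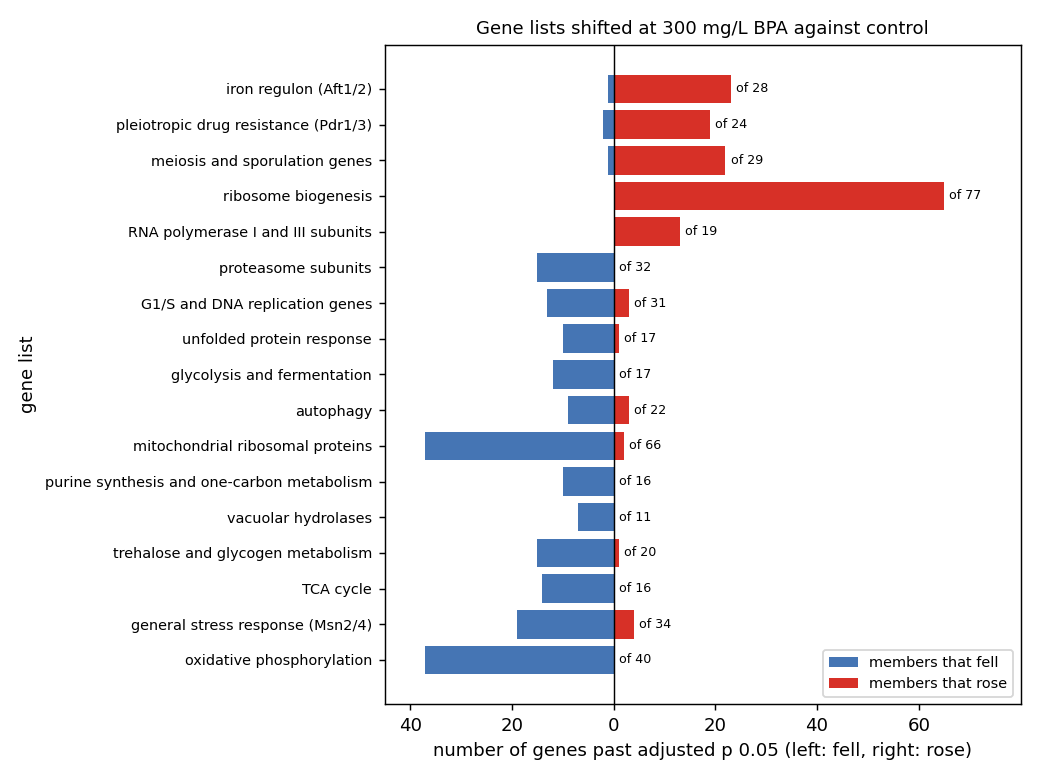
Number of genes that fell (left) and rose (right) at 300 mg/L against control in each of the 17 lists that camera called with the preset correlation, with the number measured beside each bar. The ribosome biogenesis list has 65 risers of 77, and the oxidative phosphorylation list 37 fallers of 40. With an estimated correlation 0 of these lists passed.

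Other lists split or were not called by camera. Fry put the heat shock chaperone and phosphate lists higher (adjusted p = 0.0131 and 0.00377). It did not call the oxidative stress and ergosterol lists (0.143 and 0.162). Heat shock chaperone genes had 10 of 23 higher, led by BTN2, at 3.41 ± 0.19, and SSA4, at 1.29 ± 0.28, and 3 lower, led by HSP26, by 1.20 ± 0.30 (camera adjusted p = 0.165). In the oxidative stress list 12 of 32 rose, led by the catalase CTA1, at 3.31 ± 0.31, and OYE3, at 2.43 ± 0.33, while 8 fell, led by the superoxide dismutase SOD2, by 0.89 ± 0.09. The phosphate transporter gene PHO89 rose by 3.41 ± 0.23 in a list with 7 of 15 higher and 2 lower. Of 24 ergosterol genes 8 rose and 9 fell, with ERG3 at 0.52 ± 0.09 and ERG13 lower, at -0.72 ± 0.07.

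The comparison of 50 mg/L BPA with control asks the same at the lower dose, and no gene passed. limma called 0 of 5449 genes, with 389 at an unadjusted p under 0.05 where 272 would be expected by chance. The smallest adjusted p was 0.302, for EEB1, an acyltransferase of ethyl ester synthesis, named after its value was seen. It was lower at 50 mg/L by 1.59-fold, from a control level of 8.67 ± 0.09 (SD, n = 3). With array weights, which give less to arrays that deviate, 31 genes passed, 14 higher and 17 lower. That weighting stopped before it converged.

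With the replicate number as a block among the 6 control and 50 mg/L arrays, added after seeing the data, 1 gene passed. This was YNL018C, higher by 0.76 ± 0.08, with an adjusted p of 0.0153, and 0.581 in the main fit. The same block put 2 more lists past the threshold by camera, drug resistance and ribosome biogenesis, both higher, with an adjusted p of 0.0245 for each, 0.103 in the main fit and 0.916 with the block and an estimated correlation.

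Single members of 3 lists passed at 50 mg/L when adjusted over the list alone. The drug efflux transporter genes PDR5 and YOR1 differed from control by 0.49 ± 0.11 and 0.48 ± 0.10, with an adjusted p of 0.581 for both over all genes. Of the 24 drug resistance genes 3 rose and 1 fell on that adjustment. Of 13 hexose transporters 4 fell, though HXT10, HXT13 and HXT14 lay at background on all 3 arrays at 50 mg/L and HXT14 in controls too, and of 10 zinc regulon genes 1 rose. With the block, 5 drug resistance genes rose on that adjustment, as did 1 stationary phase gene, and 1 TCA cycle gene fell. Camera put 4 lists past the threshold: mitochondrial ribosomal proteins, cytosolic ribosomal proteins and oxidative phosphorylation lower, with median changes of -0.12, -0.06 and -0.12, and G1/S genes higher, at 0.08. The adjusted p was 0.945 for each with an estimated correlation, and 0 members passed singly. Centred on hybridization spike-ins, which shifts the median gene by -0.11 at 50 mg/L, the mean change of the G1/S list was -0.0276, that of the drug resistance list -0.0064 and that of ribosome biogenesis -0.047. These signs follow from that shift.

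The comparison of 300 with 50 mg/L asks what the higher dose adds. limma called 2878 genes, 1497 higher and 1381 lower at 300 mg/L, 274 of them by at least 2-fold. SRT1 was higher by 4.73 ± 0.12, MAM1 by 4.67 ± 0.31, SPR3 by 4.49 ± 0.24 and SPO19 by 4.03 ± 0.22. YLR412C-A was higher at least 11.9-fold, since all 3 arrays at 50 mg/L were not above background. WSC4 was lower, at -2.11 ± 0.15, as were GPH1, at -2.09 ± 0.22, HXK1, at -1.88 ± 0.19, OPT2, at -1.81 ± 0.16, and HXT4, at -1.75 ± 0.18. Of the genes called against control, 1278 were also higher and 1139 also lower against 50 mg/L, where independent lists would share 412 and 348, and 0 changed direction. Both comparisons share the 300 mg/L arrays, so part of this overlap may not be a shared effect. Camera called 18 lists, and 0 with an estimated correlation. Among the 18 were cytosolic ribosomal proteins, with 39 of 127 higher and 3 lower, and zinc regulon genes, with 6 of 10 higher, such as ZPS1, at 0.92 ± 0.07. Camera's adjusted p for these lists were 0.00382 and 0.0244, and 0.644 and 0.491 with an estimated correlation. For 300 mg/L against control they were 0.271 and 0.0528 at the preset correlation.

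The changes at the 2 doses, each against the same controls, were weakly related across genes, which are not independent replicates. Pearson's r was 0.135 and Spearman's rho 0.167. Unchanged groups simulated against shared controls gave r of 0.498 ± 0.015 (SD over 100 simulations). That r assumes no change at either dose, whereas the observed changes had a variance of 0.295 at 300 mg/L and 0.0179 at 50 mg/L. It is therefore no reference for the observed r, and only the covariance can be compared. The simulated arrays were independent, so the simulated values ignore the pairing taken for the control and 50 mg/L arrays. The covariance was 0.0098 against a simulated 0.0056, a difference of 0.0043, and the slope of the change at 50 on that at 300 mg/L was 0.033. Without control replicate 3, r was 0.259, and without 50 mg/L replicate 3 it was 0.0623. With 3 controls, they could not be split into parts of 2 arrays each. How much of the relation comes from the shared controls therefore rests on the simulated covariance.

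Any difference among the 3 groups was found for 2880 genes by the F test. Centring on the hybridization spike-ins lowered the counts: 1532 genes at 300 mg/L against control, 679 higher and 853 lower, 1417 against 50 mg/L, 882 higher and 535 lower, and 1503 by the F test. Which direction held more genes also depended on the scaling. At 300 mg/L against control, repeated quantile normalization gave 1300 higher and 1629 lower, centring on S. pombe probe sets 1706 and 1158, and median centring 1414 and 1460. For 300 against 50 mg/L the same settings gave 1311 and 1612, 1688 and 1193, and 1471 and 1406. All changes are relative to the rest of each array.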

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

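The tests on ribosomal RNA below were chosen after its values were seen, as were those on the S. pombe median, the use of the alternative carbon list against the glucose explanation and the matched random lists other than the meiosis and the trehalose and glycogen ones. Probe sets outside the gene comparisons were examined for signal above the control arrays. At 300 mg/L, 3 control probe sets for ribosomal RNA were higher than in control: the 3' end of 18S by 1.05 ± 0.20, the 3' end of 25S by 1.03 ± 0.19 and the middle of 25S by 0.93 ± 0.12 on the log2 scale (SE), with adjusted p of 0.00264, 0.0019 and 0.000302 by limma. Among 3517 probe sets with no listed gene that are not control probe sets, 189 passed at 300 mg/L, 61 higher, 13 of them at least 2-fold, and 128 lower, and 0 passed at 50 mg/L.

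For the ribosomal RNA signal, a rise shared by bright genes was not seen. In 141 genes with a control level of 12 or more, the median change was -0.03. RMA makes the intensity distributions equal, which holds that median near 0 in any case. These genes therefore cannot show what the normalization did at the bright end. The 6 cre spike-in probe sets, at a control mean of 11.66, changed by a median of 0.14. All spike-ins changed by a mean of 0.0876, but their mean level of 8.47 to 8.86 per array is too low to test bright probe sets. More full-length rRNA stays open. The 5' end of 25S changed by 0.21, too close to the bound of the test for its spread. That of 18S changed by -0.14, where it lay 0.39 under the brightest rRNA probe set and the test needed 0.53. The middle of 18S, at 12.24 in controls, changed by 0.24 ± 0.09 (SE), with an adjusted p of 0.0724 by limma. That probe set was not part of the test. A difference in RNA integrity stays open too: the 3' minus 5' difference changed by a median of -0.0031 over 7 control mRNAs, but by 0.57 for TDH1, 0.26 for WBP1 and 0.19 for RIP1. The same test, planned on ACT1 and TDH1, leaves integrity open for the 2872 changed genes, with 0.57 for TDH1 and -0.0031 for ACT1, though TDH1 itself fell. Fragments of rRNA that carry a tail and so enter 3' labelling may be a biological source, which was not tested.

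The second pattern is the rise of genes with low control levels at 300 mg/L, seen in the random lists matched to the meiosis list on control level, whose median was 0.40. Of 66 genes not above background in controls 48 rose, 26 of them to above background on all 3 arrays, but a fall could hardly be called from that floor. A lift of the floor of the arrays would raise the S. pombe probe sets, whose median change was -0.0457. Unspecific hybridization would raise some of them by 1 or more, which 0% did. Their median level was 1.36, so they do not test a shift at levels such as that of SPO11, at 4.46 in controls. The median of all probe sets was higher at 300 mg/L, so a shift there stays open. The meiosis and sporulation list, with a median change of 0.64, did not stand apart from random lists of similar control level, whose central 95% reached 0.71. Those lists left out only the list's own genes, not other meiotic genes such as MAM1 and SAE3, and only medians were compared. The list's mean change was 1.14. Its rise may belong to a general rise of genes at that level, but this comparison cannot tell that from a rise of meiotic genes. An effect of the BPA dose on genes at that level stays open.

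The third pattern is the fall of carbohydrate genes. A general fall of abundant genes is argued against: the trehalose and glycogen list had a median of -0.52, below the -0.22 that bounds matched random lists. More glucose left at harvest, if BPA slowed growth, would raise HXT1 and HXT3 and lower HXT2, HXT4 and HXT7. HXT1, HXT3, HXT4 and HXT7 did so, but HXT2 rose by 1.19, and HXT6 was not measured as a gene of its own. In the list of glyoxylate, gluconeogenesis and alternative carbon genes, many of which glucose represses, 11 of 19 rose, such as PCK1, by 1.75, and 3 fell, such as MLS1, by 0.63 (camera adjusted p = 0.0528), so the explanation could be neither held nor excluded.

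Other splits of the arrays were tried for each count of genes. For 300 mg/L against control the 6 arrays gave 3266 genes and at most 0 in the other splits. For 300 against 50 mg/L they gave 2566, and at most 0 in the others. For 50 mg/L against control they gave 0, and up to 5 in the others; with 0 genes all 10 of 10 splits must give as many, so this count tests nothing. Among the splits that part all 3 same-numbered pairs, the real one gave 1 gene with the block and the other 3 gave 0, and 4 splits are too few as well. The split with 5 genes leaves pairs together. With 10 splits and 1 real one, each such design is too small for a share under 0.05. For the F test, 2 of 100 splits of the 9 arrays, the real one included, gave at least its 2880 genes. The highest other split gave 3083. This is under the planned share of 0.05. All 5 other splits that kept the 300 mg/L arrays together gave from 2602 to 3083 genes, and the 94 that broke them up gave at most 0. The rank of the real split thus depends on how control and 50 mg/L arrays are mixed, so the share does not exclude chance. The counts set the 300 mg/L arrays apart and say nothing of a difference between 50 mg/L and control.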

How the results depend on the processing

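Centring on S. pombe probe sets or on spike-ins, and the 6-array block, were chosen after seeing the data. Over 175 results for named genes, 3197 of 3281 comparisons with an alternative kept direction and side of the threshold, 79 lost the call, 5 gained one and 0 reversed. For gene lists, direction was checked only where camera called the list in the main fit or in the alternative. A list called in neither counted as kept, whatever its sign. On that basis 1725 of 1837 were kept, 59 lost the call, 49 gained one and 4 reversed. The replicate block among the 6 control and 50 mg/L arrays gave 1 gene and 6 lists and moved some calls over a list alone, as given with the results, and changed no other call. For the other comparisons the numbers did not pair the arrays: 0 of 3 same-numbered pairs with control and 1 of 3 with 50 mg/L were over 0.1 at 300 mg/L. The replicate block over 9 arrays gave 0, 2864 and 2902 genes for 50 and 300 mg/L against control and 300 against 50 mg/L. Leaving out each array gave 0 genes at 50 mg/L, 2338 to 3313 at 300 mg/L and 2408 to 2998 between doses. Array weights gave 31 genes at 50 mg/L. A 2-fold minimum left 294 and 274 genes, by its construction. Spike-in centring gave 1532, 1417 and, for the F test, 1503 genes; the cause was not tested, but this centring rests on 27 probe sets. The correlation between doses was 0.204 without the dimmest 25% of genes and 0.0623 to 0.259 with an array left out. An estimated correlation left 0, 0 and 0 shifted lists, fry gave 0, 29 and 32, and leaving out an array gave 4 to 7 at 50 mg/L, with 7 without control replicate 1 or 3. Of the 4 lists called at 50 mg/L, 3 were kept without control replicate 1 and 3 without 50 mg/L replicate 2. Reversed list means were -0.41 for mating genes between doses without the dimmest 25%, and, with spike-in centring at 50 mg/L, -0.0064 for drug resistance, -0.047 for ribosome biogenesis and -0.0276 for G1/S genes, which follow from its shift. For the mating genes the cause was not tested. Signal over background limits dim genes: of 48 risers from background, 26 reached above it on all 3 arrays.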

Other observations

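The mating and copper genes below were chosen after their values were seen, so they stand as single genes. Among genes usual in a cells at 300 mg/L, AGA2, an agglutinin subunit, rose from 3.33 ± 0.26 to 6.61 ± 0.40 (SD, n = 3), MFA2, a pheromone gene, by 1.52 ± 0.14, ASG7 by 1.37 ± 0.09 and the protease BAR1 by 1.09 ± 0.14 (SE). STE2, MFA1 and STE6 differed by 0.29, 0.23 and 0.24, with adjusted p of 0.0883, 0.0585 and 0.0853. Among genes usual in α cells, STE3, the a-pheromone receptor, fell by 0.91 ± 0.08 from 10.61, the agglutinin SAG1 by 0.63 ± 0.09 from 11.75 and the pheromone gene MF(ALPHA)1 by 0.27 ± 0.06 from 12.39, while MF(ALPHA)2 differed by -0.21 with an adjusted p of 0.0513. AGA2 was dim in controls, and genes at the meiosis list's control level rose by a median of 0.40 in random lists. HMLALPHA1, on a probe set that can match related sequences, fell by 0.43 ± 0.11 from 8.84, with an adjusted p of 0.00685, and HMRA1 lay at background on all arrays. The mating type is not given in the sources used here. As a whole, the mating list had 7 of 21 members higher and 7 lower (camera adjusted p = 0.885).

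The copper transporter gene CTR3 rose at 300 mg/L by 2.80 ± 0.09, with an adjusted p of 4.33e-08, and CTR1 by 1.35 ± 0.12. No list of copper genes was tested. At 50 mg/L they differed from control by 0.02 and -0.02.

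Whether part of the culture entered meiosis was tested with genes named in advance. IME2 and NDT80 rose by 0.40 and 0.77, and 6 of 8 recombination genes rose, or 75%, with MEI5 at background in both groups, but IME1, the first regulator, differed by 0.08 with an adjusted p of 0.621. The prediction needed all 3 regulators, so the question stays open, and the sizes were far below those of SPR3 and SPO19. In controls the α-cell genes above lay from 10.61 to 12.39, the a-cell genes from 2.61 to 5.18 and HMRA1 at background. These levels are usual in α cells, and entry into meiosis usually needs HMRA1 too, so they argue against it. The rises of IME2, NDT80 and the recombination genes go the other way. Release of silencing near chromosome ends was tested on genes not above background in controls: 55.6% of the 9 within 10 genes of an end rose, against 75.4% of the other 57 (Fisher's exact test, two-sided, p = 0.242), which decides nothing at this number. Over all genes, a comparison added later, 35.7% of 235 genes near an end rose against 27.2% of 5214 others (Fisher's exact test, p = 0.0056). Neighbouring genes are not independent, and the comparison was not matched on control level, though genes of low control level rose more widely. It therefore does not decide the question either.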
